A study of Mus musculus with 8 samples.

How the data were processed

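Poly(A) RNA of cultured mouse cardiac fibroblasts was sequenced from 8 libraries, 4 transfected with a plasmid carrying HA-tagged murine Thbs4 and 4 with an empty plasmid, per the labels. The names of the plasmids in the labels are of different constructs, so a difference between the groups is one between plasmids, of which Thbs4 is a part. Libraries were made with the NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name CASAVA, TopHat2 2.0, Cufflinks 2.1.1 and HTSeq 0.6.1 with the builds mm10 and GRCm38.p6, without saying which tool made which value. The strand setting, the annotation release and the treatment of reads that map to several genes are not given in the sources used here. Genes with near-identical copies are therefore uncertain: Gapdh, which has many processed pseudogenes, stood at only 10.6 ± 0.976 CPM with the TSP-4 plasmid. In the empty plasmid libraries A to D it stood at 11.5, 49.0, 12.8 and 11.5 CPM.

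The deposited count table holds whole-number read counts for 54532 genes, and these counts were used as the authors deposited them. The deposited FPKM table holds the authors' FPKM values, and each value equals the count divided by gene length and total, times 1 constant per library. Depth was 17123735 to 22530947 counts per library. The 95% intervals of the fold changes come from edgeR's quasi-likelihood fit and include the spread between libraries.

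The main test was edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 on counts with TMM factors, after edgeR's expression filter at its default minimum count of 10, with group as the single term and Benjamini-Hochberg adjustment at 0.05. This left 14723 genes. Gene lists were fixed before the data were examined: 40 lists with 880 entries, of which 8 were matched through RefSeq synonyms and 2 were not matched. Thbs4 was left out of every list. Lists with at least 5 tested members, 35 in all without the sex-specific transcripts, which were set beforehand to be read per library and have 5 tested members, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. For DESeq2 fits, lists were tested with camera's pre-ranked form on that fit's test statistics at the same preset correlation. List calls credited to DESeq2 thus differ from the main ones in list test as well as gene model. The genes named in the text follow a rule also fixed before: the thrombospondin family, up to 12 genes per direction past the threshold with the largest change, a mean of at least 1 CPM, an official symbol and no overlap between groups, the 5 genes with the smallest p in a direction where fewer than 3 pass, and in each list up to 4 members with the smallest p and up to 2 with the highest mean CPM where no member passes. The rule gives 221 genes. Of these, 3 are not reported here. The others entered the checks of the closing section, and the text prints a part, shortened after the values were seen.

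The test was run on simulated counts made from the real means, library sizes and dispersions, with 200 genes changed by known folds in each of 5 simulations of this comparison. Without a block it found 2% of genes changed 1.2-fold, 40% at 1.5-fold, 65.2% at 2-fold and 89.2% at 4-fold among 14551 genes, with 5.94% of calls false. These simulations gave an unchanged gene the same mean level in every library, so their libraries did not pair by letter as the real ones do. The shares without a block may therefore differ for the real data. With the replicate block it found 39.2%, 72.8%, 87.6% and 96% among 14522 genes, with 13.4% of calls false, above the nominal 5%. A first run, with 1.25-fold in place of 1.2-fold, found 6.4% at 1.25-fold, 51.6% at 1.5-fold, 72% at 2-fold and 91.2% at 4-fold without the block (7.53% of calls false), and 53.2%, 76.8%, 92% and 98.4% with it (11.6% false). A list shifted by 0.3 on the log2 scale was called in 5 of 5 simulations by either fit, with 2 other list calls in total without the block and 0 with it, and in the first run 0 by either fit. Genes were drawn independently in the simulations, so these list counts do not bear on members of a list moving together. Only the preset correlation was simulated, so how often the estimated correlation or fry finds a shifted list is not known.

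The letters A to D occur in both groups, and the labels do not say what they mark. For each letter the deviations of the paired libraries from their group means correlated across genes, which are not independent replicates, with Pearson's r from 0.508 to 0.651. Libraries of different letters lay between -0.57 and 0.323, and 8 of 8 libraries correlated best with their own letter. By the limit of 0.1 set for this check the letters pair the libraries, as found from the data and not from the labels. The fit without the block stays the main one, as fixed before the data were examined. No pair of libraries differed as little as sampling noise: the mean chi-square per gene was 2.82 or more.

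The alternatives fixed before the data were examined were DESeq2 1.42.0, limma voom, DESeq2's size factors, library totals alone, Thbs4 left out of totals and factors, no expression filter, a mean of at least 5 CPM, the replicate block, each library left out in turn, the FPKM values on the log2 scale with pseudocounts of 1 and 0.1 and with or without a minimum mean of 1, a 2-fold limit and an adjusted p of 0.01. Added after seeing the data were DESeq2 and limma voom with the block, the block with both libraries of 1 letter left out, both list alternatives with the block, and a test of genes among letters.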

Results

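Mouse cardiac fibroblasts of the C57BL/6 strain were transfected at passage 2 with a plasmid carrying murine Thbs4, which encodes the matricellular protein thrombospondin-4 (TSP-4), or with an empty plasmid as control. Cells were kept in standard medium for 12 h and deprived of serum for 24 h before RNA was collected. Poly(A) RNA was sequenced from 4 libraries per group, lettered A to D in both groups. Total counts per library ranged from 17123735 to 22530947, with a mean of 18723524 ± 2549532 (SD, n = 4) in the TSP-4 plasmid group and 19202351 ± 1702241 (SD, n = 4) in the empty plasmid group. Mitochondrial genes took 0.946 ± 0.0651% of counts with the TSP-4 plasmid and 0.928 ± 0.0357% with the empty plasmid (SD, n = 4 each). Nothing in the labels says that the libraries came from separate animals or cultures, so the p-values measure the spread between these libraries. In the main fit it includes differences between letters, which both groups share. The mean chi-square per gene was 12.0 to 45.4 within a group and 2.82 to 11.8 within a letter. Pairs that differed in both ran from 10.1 (TSP-4 plasmid C with empty plasmid B) to 44.6 (TSP-4 plasmid C with empty plasmid A). Letter means spanned 2.29 (log2) for macrophage markers, the widest range of the 35 lists, and 0.08 for cytosolic ribosomal proteins. Within a letter the macrophage mean differed by at most 0.43. For these markers this argues against a spread from library making and sequencing alone. No effect of library making was tested beyond depth and GC content.

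The comparison asked which transcripts differ in fibroblasts that overexpress TSP-4. Thbs4 itself, the gene on the plasmid, reached 1783 ± 288 CPM (counts scaled to the library total with TMM factors; SD, n = 4) with the TSP-4 plasmid and 0.327 ± 0.254 CPM (SD, n = 4) with the empty plasmid. The 4 TSP-4 plasmid libraries held 38063, 25754, 36630 and 31675 Thbs4 counts for letters A to D, and the 4 empty plasmid libraries held 2, 11, 8 and 3. The log2 fold change was 12.48 (SE 0.34, 95% interval 11.71 to 13.25), higher in 4 of 4 letters, with an adjusted p of 1.9e-06 in edgeR's quasi-likelihood test. Thbs4 (ENSMUSG00000021702) lies on chromosome 13 from 92751590 to 92794818 on the minus strand in GRCm38, a protein-coding gene whose length in the files is 3289 bp. It ranked between 25 and 51 among all genes in the TSP-4 plasmid libraries. Counts per gene cannot separate transcripts of the plasmid from those of the chromosomal gene, so the value is the sum of both.

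**Figure D1:**
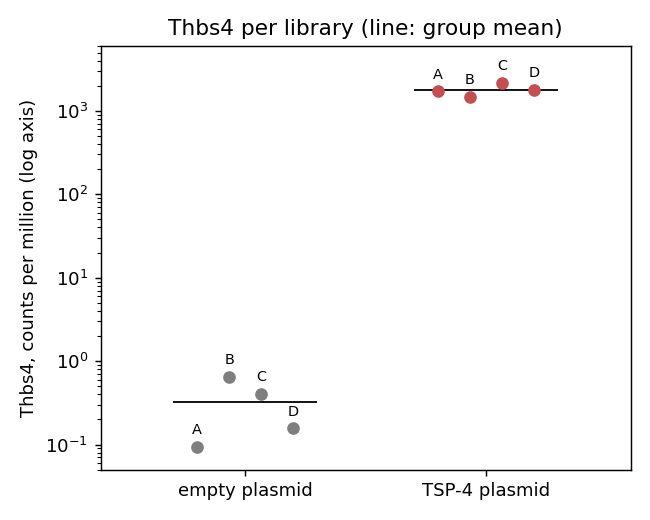
Thbs4 in CPM on a log axis for each of the 8 libraries, labelled by letter, with a line at each group mean. The TSP-4 plasmid libraries sit around a mean of 1783 and the empty plasmid libraries around 0.327.

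No other thrombospondin passed the threshold. Thbs1, the most abundant family member in these cells and an activator of latent TGF-beta, stood at 6113 ± 816 CPM with the TSP-4 plasmid and 6115 ± 871 CPM with the empty plasmid (SD, n = 4 each), a log2 fold change of -0.00 with a 95% interval from -0.29 to 0.29. Thbs2 was at 96.7 ± 42.9 against 83.3 ± 54.5 CPM, with an interval from -0.92 to 1.35 that leaves a difference of 2-fold open. Thbs3 was at 4.94 ± 1.31 against 4.11 ± 0.469 CPM, and Comp, the cartilage oligomeric matrix protein, at 1.38 ± 0.272 against 0.854 ± 0.519 CPM (interval -0.27 to 1.67). The family was too small for a list test.

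Beyond Thbs4, no gene passed the threshold in either direction. Of 14723 genes tested with edgeR, 1 was higher and 0 were lower with the TSP-4 plasmid, and the smallest adjusted p after Thbs4 was 0.999968. DESeq2 and limma voom gave the same 1 and 0. At an unadjusted p under 0.05, edgeR listed 96 genes as higher and 139 as lower, 235 in all. With the letters as a replicate block it listed 610 and 586, 1196 in all. These were 1.6% of the genes tested without the block and 8.12% with it. Exact p-values would list 5% if nothing differed. The main fit counts differences between letters as spread, so its lack of calls does not show that no other gene changed. In the simulations the fit with the block exceeded its nominal share of false calls. The genes with the smallest p that were higher without passing were Ugt1a6b (1.80 ± 0.298 against 1.06 ± 0.165 CPM), Zfp964 (2.30 ± 0.364 against 1.41 ± 0.217), Pcdhga8 (2.18 ± 0.183 against 1.39 ± 0.244), Rsph3a (9.59 ± 1.46 against 5.80 ± 1.82) and Hr (8.12 ± 0.518 against 6.35 ± 0.584). Those that were lower without passing were Nfil3, a circadian bZIP repressor (26.7 ± 1.26 against 31.3 ± 1.07 CPM), the DNA polymerase alpha subunit Pola2 (14.8 ± 1.29 against 18.5 ± 0.687), the methyl-CpG binding protein Mbd2 (107 ± 3.08 against 129 ± 12.9), the phosphatase subunit Ppp2cb (91.2 ± 8.74 against 110 ± 7.47) and Tyw1 (means of 41.5 against 46.8; SD, n = 4 for each gene given with one). The 95% interval of the fold change lay within 2-fold for 13014 genes (88.4%), and for 9092 of the 9324 genes at a mean of at least 10 CPM (97.5%). Groups did not overlap for 223 genes (1.51%). The 2.86% expected by chance holds for 8 exchangeable libraries, and these pair by letter. With the letters as a replicate block, edgeR called Thbs4 higher and 1 gene lower: Ybx3, a cold-shock domain RNA-binding protein, at 296 ± 43.1 against 362 ± 34.5 CPM (log2 fold change -0.29, adjusted p 0.0374, lower in 4 of 4 letters; not called with the block without letter B, C or D), a gene outside the naming rule and chosen after its values were seen. It was also called with the block by DESeq2 (adjusted p 0.000167), by limma voom (0.0363) and by edgeR without letter A (0.0195).

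**Figure D2:**
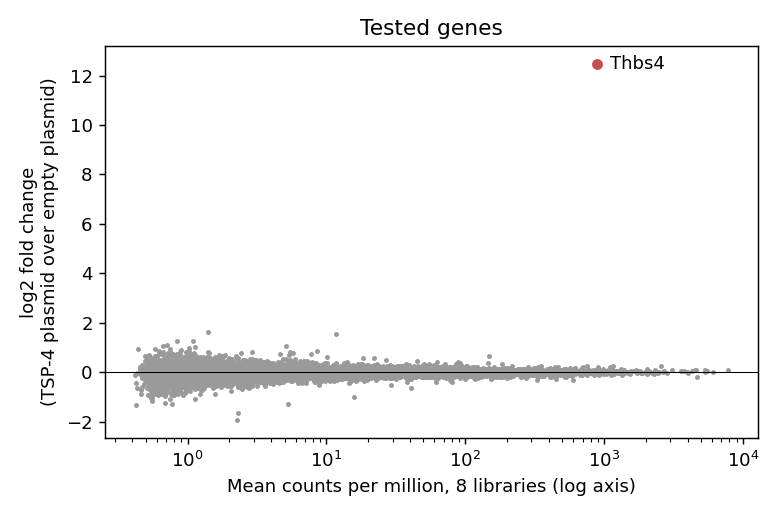
Log2 fold change (TSP-4 plasmid over empty plasmid) against the mean CPM of the 8 libraries on a log axis, 1 point per tested gene. Thbs4 stands at 12.48 and is the 1 gene past the threshold.

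Among 35 gene lists tested with camera at a preset correlation of 0.01, 4 were called. Immediate-early genes, the fast transcriptional response to growth factors and stress, were lower: 24 of 26 members lay below 0, with a median log2 fold change of -0.16 and an adjusted p of 4.7e-08. Interferon-stimulated genes were higher (40 of 44 above 0, median 0.07, adjusted p 0.0019), as were genes of cholesterol biosynthesis (23 of 23 above 0, median 0.15, adjusted p 0.0245) and fibrillar and other collagens (16 of 19 above 0, median 0.12, adjusted p 0.0265). With an estimated correlation 0 lists were called, and the adjusted p was 0.967 for each of these 4. How often that test finds a shifted list was not simulated. No member of any list passed over all genes, and 0 passed when adjusted over the list alone in these 4 lists. Camera called 11 lists with the replicate block and the preset correlation, and 0 with the block and an estimated correlation (smallest adjusted p 0.935). With each of the 8 libraries left out in turn and no block, immediate-early genes kept their call in 8 fits (median -0.26 to -0.11), interferon-stimulated genes in 5, cholesterol biosynthesis in 4 and collagens in 2. The interferon median fell to -0.012 without TSP-4 plasmid library C and -0.018 without empty plasmid library A. Cholesterol biosynthesis fell to 0.012 without TSP-4 plasmid library A, where camera gave the other direction (adjusted p 0.976), and collagens fell to 0.024 without empty plasmid library D. Over these fits the median lay on both sides of 0 for 26 of the 35 lists. Leaving out 1 library unbalances the letters, so such shifts mix letters with plasmids. Cholesterol biosynthesis averaged highest in letter A (0.34 from the mean). With the block and both libraries of letter A, B, C or D left out, it and immediate-early genes were called each time at the preset correlation. Interferon-stimulated genes were then not called without letter A or C, nor collagens without C.

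Among immediate-early genes, Fos, a subunit of AP-1, stood at 8.59 ± 0.977 against 10.9 ± 1.15 CPM (log2 fold change -0.34), Egr3 at 1.89 ± 0.252 against 2.76 ± 0.328 CPM (-0.55), Ier5 at 87.8 ± 2.26 against 95.9 ± 1.92 CPM (-0.13) and the nuclear receptor Nr4a2 at 7.13 ± 1.52 against 9.30 ± 0.714 CPM (-0.38; SD, n = 4). These 4 members had an unadjusted p under 0.05 and none passed the adjusted threshold. With the replicate block, 14 members were lower when adjusted over the list alone and 0 over all genes. Fosl2, the most abundant member, was at 312 ± 5.34 against 304 ± 4.94 CPM. Among cholesterol genes, Hmgcs1 (77.5 ± 20.1 against 67.5 ± 13.7 CPM), the squalene synthase Fdft1 (51.4 ± 15.3 against 43.9 ± 10.6) and Srebf2, a master regulator of sterol synthesis (173 ± 21.4 against 161 ± 20.6), did not pass. With the block, 7 members were higher when adjusted over the list alone. Among interferon-stimulated genes, Ifit3 (1182 ± 170 against 1017 ± 156 CPM), Mx2 (81.7 ± 8.15 against 73.4 ± 9.63) and the regulator Irf7 (1129 ± 72.9 against 1076 ± 110) did not pass. Among collagens, Col8a2 (2.09 ± 0.657 against 1.30 ± 0.403 CPM), Col12a1 (275 ± 21.3 against 251 ± 30.5) and Col1a1, the main chain of fibrillar collagen type I (5498 ± 610 against 5196 ± 654), did not pass.

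**Figure D3:**
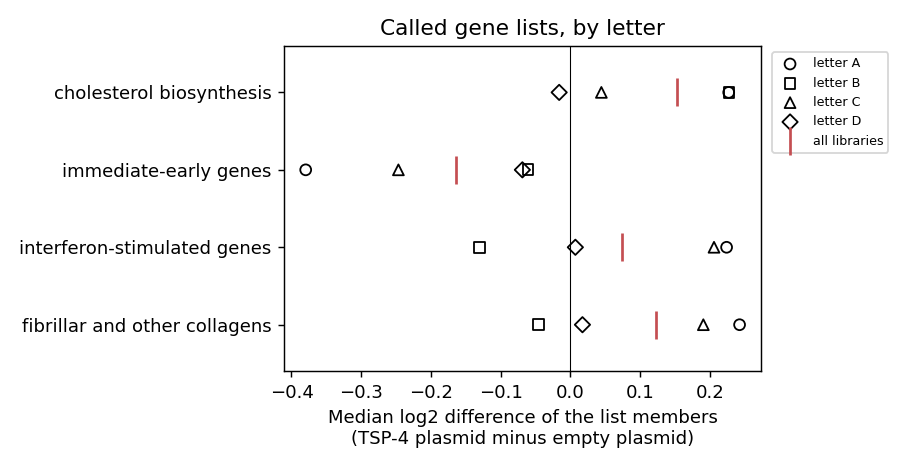
Median log2 difference (TSP-4 plasmid minus empty plasmid) of the members of the 4 called lists, for each letter and over all libraries. Immediate-early genes lie below 0 in 4 of 4 letters (-0.38, -0.06, -0.25 and -0.07 for A to D), and each of the other lists keeps its direction in 3 of 4. The lists were called on these same values, so agreement between letters adds no support.

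Matrix and fibroblast activation genes outside the collagens gave no call in the main fit. Matricellular and other matrix proteins had a median log2 fold change of 0.05 (21 of 33 above 0), with fibronectin Fn1 at 8173 ± 1578 against 7557 ± 1141 CPM, and collagen processing and cross-linking genes 0.06 (16 of 18 above 0), with the cross-linking enzyme Lox at 3676 ± 387 against 3515 ± 195 CPM. Matrix proteases and their inhibitors had a median of -0.01, with Timp1 at 2053 ± 396 against 2084 ± 515 CPM. The TGF-beta pathway and target genes had a median of -0.01 (13 of 27 above 0), with Ctgf at 2258 ± 283 against 2355 ± 409 CPM. Myofibroblast and contractile genes stood at -0.01 (10 of 22 above 0; Vim at 3950 ± 233 against 3903 ± 271 CPM), and integrins and focal adhesion genes at 0.00 (16 of 30 above 0; Itgb1 at 1724 ± 117 against 1716 ± 53.5 CPM). With the replicate block, camera called the matricellular list (adjusted p 0.0139) and the collagen processing list (0.00848) as higher, and neither with an estimated correlation (adjusted p 0.935 and 0.936). Without the block, DESeq2 called the collagen processing list (adjusted p 0.0292), and both lists were called without TSP-4 plasmid library D and without empty plasmid library B.

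Stress, immune and growth lists other than the immediate-early and interferon lists gave no call in the main fit. The unfolded protein response and ER chaperones had a median of 0.00, with Hspa5, the ER chaperone BiP, at 906 ± 40.3 against 927 ± 88.0 CPM. Amino acid response genes had a median of -0.07 (5 of 17 above 0), cytokines, chemokines and NF-kB targets -0.07 (6 of 34), cell cycle and proliferation genes -0.10 (4 of 40; Ccnd1 at 902 ± 143 against 914 ± 92.5 CPM), complement genes 0.07 (10 of 11) and the Wnt pathway 0.07 (16 of 21). With the replicate block, camera called these 5 lists at adjusted p 0.0192, 0.00445, 0.000169, 0.0129 and 0.0423, and none with an estimated correlation. Without the block, DESeq2 called the cell cycle list as lower (adjusted p 0.0285). With 1 library left out the cell cycle list was called in 3 of 8 fits, cytokines and complement genes in 2 each. Their medians ranged from -0.21 to 0.09, -0.25 to 0.13 and -0.13 to 0.41 over the 8 fits. The Wnt, MHC class I and heat shock lists, cytosolic ribosomal proteins and mitochondrially encoded mRNAs were called in 1 fit each. With the block, camera called growth factors and receptors as higher from the DESeq2 fit (adjusted p 0.00721) and the limma voom fit (0.0365). Medians were 0.01 for antigen presentation by MHC class I, -0.00 for p53 targets, 0.03 for glycolysis and hypoxia, 0.04 for growth factors and receptors, -0.00 for NRF2 and antioxidant genes, -0.02 for heat shock chaperones, 0.03 for lysosome and autophagy genes and 0.06 for cytosolic DNA sensing, a route by which transfected DNA is detected. Fatty acid oxidation and PPAR targets stood at -0.00, mitochondrially encoded mRNAs at 0.05, nuclear oxidative phosphorylation genes at -0.01 and cytosolic ribosomal proteins at -0.01.

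No list of cell type markers was called between the groups in the main fit. Resident cardiac fibroblast markers had a median of 0.04 (12 of 16 above 0), with Gsn at 538 ± 18.4 against 524 ± 35.3 CPM; without empty plasmid library B the median was 0.40 and the list was called higher (adjusted p 0.0029). Macrophage markers stood at 0.04, with the lysozyme gene Lyz2 at 524 ± 355 against 496 ± 279 CPM, and were called higher without TSP-4 plasmid library A (0.33, adjusted p 0.0123) and lower without TSP-4 plasmid library C (-0.50, adjusted p 0.0193). Endothelial markers stood at -0.03, pericyte and smooth muscle markers at 0.07, epicardial and mesothelial markers at 0.04, Schwann cell markers at 0.03, and chondrocyte and bone genes at 0.07. With 1 library left out these 5 medians ranged from -0.20 to 0.04, -0.18 to 0.15, -0.10 to 0.23, -0.07 to 0.04 and -0.07 to 0.19. Cardiomyocyte markers had 3 tested members and adipocyte markers 2, too few for the list test, with medians of -0.05 and 0.03. Of the T, B and NK cell markers 0 passed the expression filter. The sex-specific transcripts were read per library only: Xist lay between 77.1 and 160 CPM and the Y-linked Ddx3y between 62.8 and 69.6 CPM over the 8 libraries. The median, the mean and the test differed in sign for 8 uncalled lists, which were matrix proteases, the unfolded protein response, MHC class I, fatty acid oxidation, NRF2, macrophages, pericytes and Schwann cells.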

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

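Chance flags about 5% of groups of 4 libraries, and 26 of the 512 values examined (named genes, list means, total counts and mitochondrial share in each group) had 1 library far from the other 3, so their number is near what chance gives. Each value below is that library's gap to its nearest neighbour as a share of the group's range. In the TSP-4 plasmid group library A stood apart for total counts (0.897; 22530947 against at most 17681837), Serpinh1 (0.91), Lif (0.841), Ccng1 (0.862), Ier5 (0.864) and Mt1 (0.837). Library B stood apart for Msln (0.871). Library C did for Ugt1a6b (0.925), Eno1 (0.85), Atp5a1 (0.859) and the mean of cytosolic ribosomal proteins (0.95). Library D did for Col8a2 (0.852), Shmt2 (0.895), Maff (0.853), Lamp2 (0.847), Esam (0.845) and Krt18 (0.851). In the empty plasmid group library A stood apart for Serpinh1 (0.839), Igfbp2 (0.837), Wnt5b (0.868) and Map1lc3b (0.872), and library B for Pola2 (0.852), Rrm1 (0.876), Ier5 (0.934), Gapdh (0.922; 49.0 CPM) and the mean of the unfolded protein response list (0.833). Serpinh1 was highest in letter A of both groups.

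The tests of gene and list counts against other groupings were set before their results were seen, and the test of list members moving together was chosen after. The real grouping called 1 gene, Thbs4, with 25754 to 38063 counts against 2 to 11. Of the 35 splits of the 8 libraries into 4 and 4, 4 called at least 1 gene, so the number of calls taken alone does not exclude chance; it does not bear on Thbs4 itself. The highest other split called 1771 genes, which points to a structure of the samples: the 3 other splits with a call keep the libraries of each letter together and called between 4 and 1771. Among the 8 splits that part all 4 letters the other 7 called 0. For gene lists, 31 of the 35 splits called at least the real 4, and the highest other, which keeps letters together, called 20. Splits that do not part all 4 letters also carry the differences between letters, so this share does not measure chance for the real grouping. Among the 8 splits that part all 4 letters, too few for a share under 0.05, 4 called at least 4 lists, the real one included, and the highest other called 6. Chance is therefore not excluded. With the replicate block the 8 exchanges of labels within letters are too few for a share under 0.05: the real labels called 2 genes and 11 lists, 2 exchanges called at least as many genes and 4 at least as many lists, the real one included, and the highest other exchange called 2 genes and 15 lists. Members of a list moving together between libraries may account for the list calls: 0 of the 4 called lists passed with an estimated correlation. That test was not run on simulated shifts, so its 0 calls may also come from a test that finds little. Without the block its estimate also takes in the differences between letters. For a difference between the plasmids, the lowest number of letters with a list's direction over the 4 called lists was 3, between the bounds set. The lists were called on these same values, so agreement between letters adds no support. A difference between the plasmids cannot be told apart from chance by this value.

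Lower immediate-early genes were picked out after the list test, and the tests were set before the values per letter were seen. Their median difference was below 0 in 4 of 4 letters. The list was picked on these same values, so this does not support a difference between the plasmids beyond the list test, and it leaves one open. Against a chance difference between the libraries of a letter, 0 of the 7 other exchanges within letters gave a mean list t as far from 0 (real -2.41, highest other 1.89 in size). The bound written for that test was too loose, since 8 exchanges cannot give a share under 0.05, so chance stays open. For each of the other called lists, at least 1 other exchange gave a mean list t farther from 0 than the real labels. The highest was 2.85 against a real 1.28 for interferon-stimulated genes, with letters B and D exchanged. It was 2.04 against 1.58 for collagens (B exchanged) and 2.104 against 2.028 for cholesterol biosynthesis (D exchanged). The TSP-4 protein and other differences between the constructs are confounded by the design.

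Libraries of the same letter deviated together. The tables argue against library depth, since the lowest same-letter correlation was 0.496 with all libraries thinned to 17123735 counts. They argue against GC content likewise, with 0.505 after a trend on GC was removed from each library over 14711 genes. What the letters mark is not given in the labels, and no biological explanation was tested.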

How the results depend on the processing

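Thbs4 was called higher in 25 of 25 alternatives that tested every gene, with a log2 fold change of 12.14 to 13.09 on counts and 8.93 to 11.48 on log2(FPKM + pseudocount), which understates low genes. It was the 1 gene called in 18 of the 19 alternatives fixed beforehand, the replicate block being the exception with 1 lower gene. Of those added after seeing the data, DESeq2 with the block called 6 higher and 4 lower, limma voom with the block 1 lower, and the block without letter A 2 higher and 3 lower, without letter B 3 higher and 1 lower, and without letter C 1 lower. Leaving out each library in turn gave 1 higher and 0 lower throughout, with 161 to 626 genes at an unadjusted p under 0.05. The number of called lists, 4, was 2 with no filter and 2 with unfiltered FPKM, 11 with the replicate block, 13 with DESeq2 and the block, 12 with limma voom and the block, 13 with the block without letter B, 11 without letter D, and 0 with an estimated correlation or fry, with or without the block. Leaving out 1 library gave 2 to 11 lists: 8 without TSP-4 plasmid library D, 11 without empty plasmid library B and 2 without empty plasmid library C. Cholesterol biosynthesis turned direction in camera without TSP-4 plasmid library A, and its median ranged from 0.012 to 0.29 over the libraries left out in turn. The macrophage list, whose median then ranged from -0.50 to 0.38, was called higher without that library (0.33) and with the block without letter B (0.16), and lower without TSP-4 plasmid library C (-0.50). Resident cardiac fibroblast markers were called higher without empty plasmid library B (0.40), with DESeq2 and the block (0.07) and with the block without letter B (0.13). Leaving out 1 library without the block unbalances the letters. Macrophage markers averaged lowest in letter A (-1.25 from the mean, log2 scale) and highest in C (1.04), and fibroblast markers highest in B (0.65). For both lists the calls with 1 library left out take the direction that these letter differences give. They cannot be credited to the plasmids. The cause of the calls with the block was not tested. Immediate-early genes were called in 25 of 29 alternatives, the 4 others being the estimated correlation and fry, interferon-stimulated genes in 20, cholesterol biosynthesis in 19 and collagens in 13. The collagen call was lost in 6 of the 8 fits with 1 library left out (median down to 0.024), with no filter, at a mean of at least 5 CPM (adjusted p 0.0538), in the 3 FPKM fits, with the block without letter C, and with the estimated correlation and fry. Among 219 genes followed, Ybx3, Fmod and Mbd2 passed in some fits with the block and in none without it, and the edgeR fit with the block on all libraries changed no other call than that of Ybx3. In the simulations 40% of 1.5-fold changes were found without the block (51.6% in a first run) and 72.8% with it, and 2% and 39.2% of 1.2-fold changes. Changes of 1.2-fold were thus mostly out of reach of the main fit there. The libraries simulated without the block did not pair by letter, so its shares may differ for the real data.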

Other observations

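The letters differed in macrophage, resident fibroblast and mesothelial markers by more than the libraries of 1 letter differed between plasmids, in a test chosen after seeing the data. The ranges of letter means were 2.29, 1.08 and 0.52 on the log2 scale, against at most 0.43, 0.18 and 0.08 between the plasmids within a letter. Endothelial markers (0.22 against 0.24) and Schwann cell markers (0.35 against 0.31) did not show this clearly. Of 14723 genes, 4134 (28.1%) differed among the 4 letters in edgeR with group in the model. The macrophage list had the widest range of letter means among the 35 lists, with 15 of 16 members differing. Lyz2 averaged 182, 515, 928 and 416 CPM in letters A to D, the complement component C1qb 18.2, 55.4, 103 and 39.5 CPM, and the lysosomal marker Cd68 20.9, 47.6, 68.7 and 37.7 CPM. In both plasmid groups Lyz2 and C1qb were lowest in letter A and highest in letter C.

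Cytokines, chemokines and NF-kB targets spanned 1.33 among letters (29 of 34 members differing), with the adhesion molecule Vcam1 at 826, 1589, 1816 and 1114 CPM, and complement genes 1.12, with C3 at 294, 1008, 789 and 352 CPM. Resident cardiac fibroblast markers spanned 1.08. The mesothelial gene Upk3b went another way, at 319, 159, 181 and 237 CPM. Cytosolic ribosomal proteins spanned 0.08 and nuclear oxidative phosphorylation genes 0.07, with 2 of 37 members differing. Xist and the Y-linked Ddx3y were both read in every library, and Xist differed among letters (adjusted p 5.5e-06 in edgeR; 77.1 and 93.6 CPM in letter D, 139 to 160 CPM in the others) while Ddx3y gave an adjusted p of 0.902.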
